A study of Mus musculus with 50 samples.

How the data were processed

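The series holds 50 Affymetrix oligonucleotide arrays of mouse brain, 25 of neocortex and 25 of hippocampus. Each tissue was sampled from 10 wild-type mice, 10 mice labelled S1P2-KO and 5 mice labelled S1P3-KO, all 8 weeks old. S1P2 and S1P3 are cell surface receptors for sphingosine 1-phosphate, a signalling lipid, and are encoded by S1pr2 and S1pr3. The wild-type and S1P2-KO groups hold 5 males and 5 females each, and the S1P3-KO group holds 2 males and 3 females. Groups, sexes and replicate numbers were taken from the sample titles, which call the replicates biological. The design text lists the group sizes as 10, 5 and 10 and names the S1P2-deficient mice where the S1P3-deficient mice would stand, so the titles were followed. Per the labels' protocols, total RNA was extracted with TRIzol and 12 µg of it was turned into biotin-labelled cRNA.

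The authors deposited 1 intensity value per probe set and array, on a linear scale, for 12488 probe sets. Per the submitters' processing notes these intensities are MAS5 signals, for which no software version is given in the sources used here. MAS5 subtracts a mismatch signal for each probe and scales whole arrays, which makes low signals noisy. The deposited intensities had already been scaled: the mean signal after trimming 2% at either end lay between 1000.56 and 1000.66 on every array, so no further scaling was applied. The table held no detection calls. Median signals ran from 299.6 to 413.8, and no pair of arrays held identical values (highest rank correlation 0.97). For arrays there is no read depth, and the number of arrays limits the precision.

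Probe sets were named through the platform annotation given with the data. Of all probe sets, 10855 had 1 gene symbol, 396 had several and 1237 had none here, and 10839 of those with 1 symbol were matched by gene identifier to the RefSeq table of assembly GRCm38.p6, with 0 symbols changed. That table served only for names and for which genes lie near each other, and no genome coordinates are given. Probe sets with several genes or none were not named as genes. A gene stands by its probe set with the highest mean level over the 50 arrays. The arrays also carry control probe sets at the 3' and 5' ends of the Gapdh and beta-actin transcripts. The mean log2 ratio of 3' to 5' signal over these 2 transcripts was taken as a measure of RNA integrity, since degraded or poorly copied RNA raises it.

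The computed values are log2(signal + 30.7), where 30.7 is the 10th percentile of all deposited signals, so log2 differences of dim genes are understated. Probe sets entered the tests when their mean over the 50 arrays lay above the pooled 30th percentile, which left 8534 probe sets for 6350 genes after removal of 66 control probe sets. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean trend), in each tissue over the 3 genotypes with sex as a covariate, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The wild-type tissues, and genotype effects between tissues, were compared in 1 model of all 50 arrays with a mean for each genotype and tissue and with sex within tissue. Genotype effects between sexes came from a model of each tissue with that interaction. All adjusted p-values of single genes are from limma.

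Before the data were examined, 29 gene lists were fixed for signalling through the receptors, neuronal activity, cell types, tissues that a dissection could carry along, synapses and channels, metabolism, stress and the neighbourhood of either receptor gene. They were tested with camera of limma with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. A second camera test estimated the correlation between genes from the data. After the data were seen, the mean log2 level of each list was also computed per array and compared between genotypes by two-sided permutation of the arrays, exactly where a group held 5 arrays and with 1e+05 resamples for 10 against 10. These tests ask whether a list differs between arrays and do not set it against other genes.

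The genes named in the text follow a rule fixed at the same time. It takes S1pr2 and S1pr3 in every comparison and, past the threshold, up to 10 genes with the largest rise and 10 with the largest fall. It also takes up to 4 members of each list past the threshold, or the 2 members with the smallest p where a list passed and no member did, and the sex-linked genes for the comparison of sexes. Genes named with an alternative or with replicate values are the few that it called. Few genes passed the threshold in the knockouts, so most genes named there are such list members. Ppan, Spock1 and the genes of the fits over both tissues were chosen after their values were seen.

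The calling procedure was tested on simulated data in which 66 or 67 of the 8534 probe sets were shifted by each of 3 sizes. With the spread and group sizes of wild-type and S1P2-KO neocortex it recovered 59.7% of shifts of 0.5 on the log2 scale, 91.0% of shifts of 1 and 98.5% of shifts of 2. In hippocampus it recovered 49.3%, 85.1% and 100%. For S1P3-KO against wild-type the shares were 43.3%, 95.5% and 100% in neocortex and 43.3%, 74.6% and 100% in hippocampus. False calls made up 3.1% to 7.3% of all calls. The simulated noise was normal and independent between probe sets, with no effect shared by a whole array. These shares describe such noise and are not error rates for the real arrays.

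Alternatives to the offset, the filter on dim probe sets, the normalization, the variance prior, equal array weights, the covariates and the samples in the fit were listed before the data were examined. Leaving out the hippocampus arrays with the highest 3' to 5' ratios, the list means, a fit over both tissues with the replicate number as a block and a fit of the averages of both tissues were added afterwards. All 50 arrays were used.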

Results

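Gene expression was measured in neocortex and hippocampus of adult mice that lacked a receptor for the signalling lipid sphingosine 1-phosphate. Mice deficient in S1P2 have sporadic seizures at 4 to 7 weeks of age, whereas mice deficient in S1P3 do not, and tissue was taken at 8 weeks. The design therefore asks which transcripts differ in either knockout, and which of these differences go with the genotype that had seizures. Each tissue was represented by 10 wild-type arrays, 10 arrays labelled S1P2-KO and 5 arrays labelled S1P3-KO. Values are MAS5 signals on a linear scale, given as mean ± SD, and differences are log2 estimates ± SE from limma on 8534 probe sets.

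In neocortex the mean log2 ratio of 3' to 5' control signal, a measure of RNA integrity, lay between 0.01 and 0.61 on all 25 arrays. Its median was 0.38 in wild-type (0.30 to 0.48), 0.26 in S1P2-KO (0.01 to 0.61) and 0.24 in S1P3-KO (0.21 to 0.36), so the ratio went partly with genotype and both knockout medians lay below every wild-type array. In hippocampus 3 arrays stood above a ratio of 1, with 1.2 in wild-type replicate 4, 1.37 in S1P2-KO replicate 7 and 4.46 in S1P3-KO replicate 5. The last of these also had the lowest median correlation of log2 signals with the other arrays of its tissue, 0.85, against at least 0.926 for every other array of the series. It stayed in the comparisons, and values without it are given for the genes and lists most exposed to it. The sex labels were checked with Eif2s3y, a translation factor gene on the Y chromosome. Its signal was at least 421.9 on every male array and at most 128.2 on every female array, so 0 arrays went against their label.

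**Figure D1:**
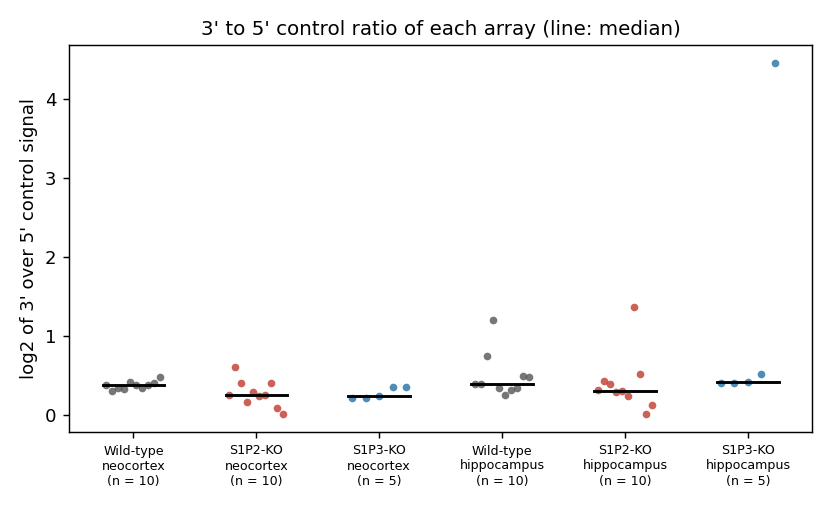
Each point is 1 array, the horizontal axis gives genotype and tissue with the number of arrays, and the vertical axis gives the log2 ratio of 3' to 5' control signal averaged over Gapdh and beta-actin. Black lines are group medians, which run from 0.24 to 0.42, and the single array at 4.46 is S1P3-KO hippocampus replicate 5.

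The targeted genes were examined first. S1pr2, which encodes S1P2 and is read by 1 probe set, was not measurably lower on the arrays labelled S1P2-KO. In neocortex its signal was 672 ± 137 in wild-type and 628 ± 147 in S1P2-KO (n = 10 each), a difference of -0.10 ± 0.14 (limma adjusted p = 0.874, 95% interval -0.39 to 0.19). In hippocampus it was 649 ± 173 and 542 ± 144, a difference of -0.24 ± 0.16 (adjusted p = 0.925, interval -0.57 to 0.09). Whether this probe set lies in the deleted part of the gene is not known here, and if it lies outside, it says nothing on the genotype. S1pr3, which encodes S1P3, was 827 ± 204 in wild-type hippocampus (n = 10) and 495 ± 42.7 on the 5 arrays labelled S1P3-KO. The difference of -0.69 ± 0.18 missed the threshold after adjustment (limma adjusted p = 0.164, interval -1.05 to -0.32), and all 5 S1P3-KO arrays lay below the wild-type median of 860. Without replicate 5 S1pr3 differed by -0.65 ± 0.19 (limma adjusted p = 0.312). In neocortex S1pr3 was 859 ± 168 in wild-type and 729 ± 242 in S1P3-KO, a difference of -0.26 ± 0.17 (adjusted p = 0.638). The genotypes therefore rest on the labels, and every direction given for a knockout refers to the arrays labelled so. The other measured receptors of the family, S1pr1 for sphingosine 1-phosphate and Lpar1 for lysophosphatidic acid, differed from wild-type by -0.06 and 0.12 in S1P2-KO neocortex, and neither passed the threshold.

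**Figure D2:**
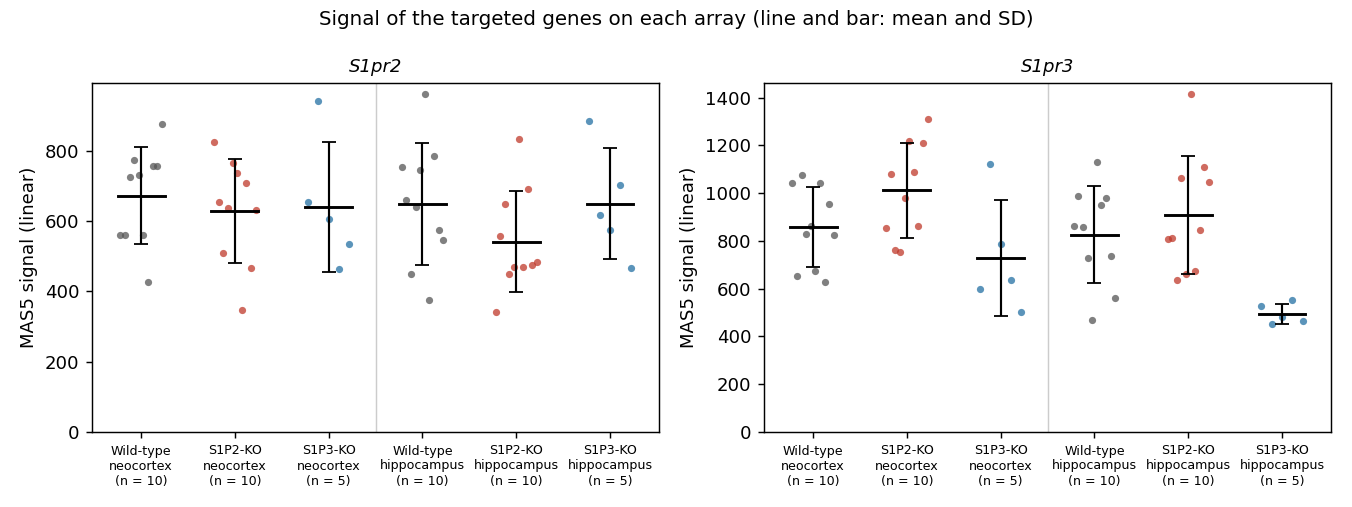
Signal of S1pr2 (left) and S1pr3 (right) on each array, with the linear MAS5 signal on the vertical axis and genotype and tissue on the horizontal axis; points are arrays, and black lines and bars are means and SD. S1pr2 overlaps between all groups, and S1pr3 in S1P3-KO hippocampus lies between 451 and 552, below the wild-type mean of 827.

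In neocortex labelled S1P2-KO, immediate early genes, the transcripts that neurons induce within minutes of activity, were lower than in wild-type. Of 29 measured members 24 were lower and 5 higher, and the list fell (camera adjusted p = 3.05e-08, and adjusted p = 0.268 with an estimated correlation). The list mean differed by -0.32 ± 0.13 between 10 and 10 arrays. Fos, an AP-1 transcription factor gene and a common marker of recent neuronal firing, was 3142 ± 1570 in wild-type and 1187 ± 544 in S1P2-KO, a difference of -1.32 ± 0.27 (limma adjusted p = 0.0764). All 10 S1P2-KO arrays lay below the wild-type median of Fos. Egr1, another activity-induced transcription factor gene, differed by -0.57 ± 0.14 (adjusted p = 0.194; 10220 ± 2370 and 6791 ± 1220). The permutation test of the list mean gave p = 0.0304 (0.147 after adjustment over 29 lists). Adjusted over the list alone, 12 members were lower and 1 was higher, while 0 passed over all genes.

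Astrocyte markers rose in the same neocortex arrays (camera adjusted p = 0.00277, and adjusted p = 0.0478 with an estimated correlation). Of 22 members 15 were higher and 7 lower, the list mean differed by 0.11 ± 0.03, and 9 of the 10 S1P2-KO arrays lay above the wild-type median of that mean. Its permutation p was 0.00383 (adjusted 0.0432), and 7 members passed when adjusted over the list alone. Gfap, the intermediate filament of astrocytes, was 1112 ± 242 in wild-type and 1523 ± 218 in S1P2-KO, a difference of 0.47 ± 0.13 (limma adjusted p = 0.235). Gjb6, the gap junction protein connexin 30 of astrocytes, differed by 0.27 ± 0.08 (adjusted p = 0.235). The list holds the metallothioneins Mt1 and Mt2, which also stand in the glucocorticoid list. With the mean of all probe sets of a gene in place of the brightest, the adjusted p of the list was 0.0615. The list of reactive astrocyte genes, which also holds Gfap, did not pass (adjusted p = 0.544).

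Glutamate receptors and their scaffold proteins also rose in S1P2-KO neocortex, with 14 of 19 members higher (camera adjusted p = 0.00277, and adjusted p = 0.218 with an estimated correlation). The list mean differed by 0.16 ± 0.06 (permutation p = 0.0114, adjusted 0.07). Grin2b, an NMDA receptor subunit, was 899 ± 168 in wild-type and 1212 ± 351 in S1P2-KO, a difference of 0.38 ± 0.14 (limma adjusted p = 0.399). Dlg4, the postsynaptic scaffold PSD-95, differed by 0.43 ± 0.17 (adjusted p = 0.448). Genes of cholesterol synthesis fell, with 13 of 16 members lower (camera adjusted p = 0.0156, and adjusted p = 0.218 with an estimated correlation). Their mean differed by -0.13 ± 0.04 (permutation p = 0.00447, adjusted 0.0432). Mvd, which makes isopentenyl pyrophosphate from mevalonate diphosphate, was 928 ± 153 in wild-type and 586 ± 116 in S1P2-KO, a difference of -0.64 ± 0.13 (limma adjusted p = 0.0764), and all 10 S1P2-KO arrays lay below its wild-type median. Cyp51, the lanosterol demethylase, differed by -0.30 ± 0.14 (adjusted p = 0.517). Without S1P2-KO replicate 2 the adjusted p of the cholesterol list was 0.058.

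No single probe set passed the limma threshold in S1P2-KO neocortex, where 0 of 8534 were called and 746 had an unadjusted p under 0.05. The count rested on single animals: it was 8 without wild-type replicate 6, 5 without wild-type replicate 7 and 2 without S1P2-KO replicate 2. With array weights it was 8, among them Fos, Mvd and Gadd45b, and with the 3' to 5' ratio as a covariate it was 1. The next list after the 4 that passed was choroid plexus (adjusted p = 0.0779). The list of neuropeptides and trophic factors that respond to seizures, which holds Npy, Bdnf and Penk, did not pass (adjusted p = 0.514), and its mean differed by 0.07 ± 0.05.

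In hippocampus labelled S1P2-KO, immediate early genes were also lower, with 23 of 29 members lower and 6 higher (camera adjusted p = 6.18e-06, and adjusted p = 0.0964 with an estimated correlation). Both tissues may come from the same animals, so this need not be an independent repeat of the neocortex result. The list mean differed by -0.25 ± 0.08 (permutation p = 0.00748, adjusted 0.0723), and on all 10 S1P2-KO arrays it lay below the wild-type median. Nr4a1, an activity-induced nuclear receptor gene, was 2113 ± 914 in wild-type and 961 ± 233 in S1P2-KO, a difference of -1.01 ± 0.22 (limma adjusted p = 0.282). Fos was 1182 ± 829 and 402 ± 87.8, a difference of -1.23 ± 0.28 (adjusted p = 0.404). Without the 3 arrays of high 3' to 5' ratio the list mean differed by -0.20 ± 0.08 (permutation p = 0.0246), and the list still passed (camera adjusted p = 0.00379).

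**Figure D3:**
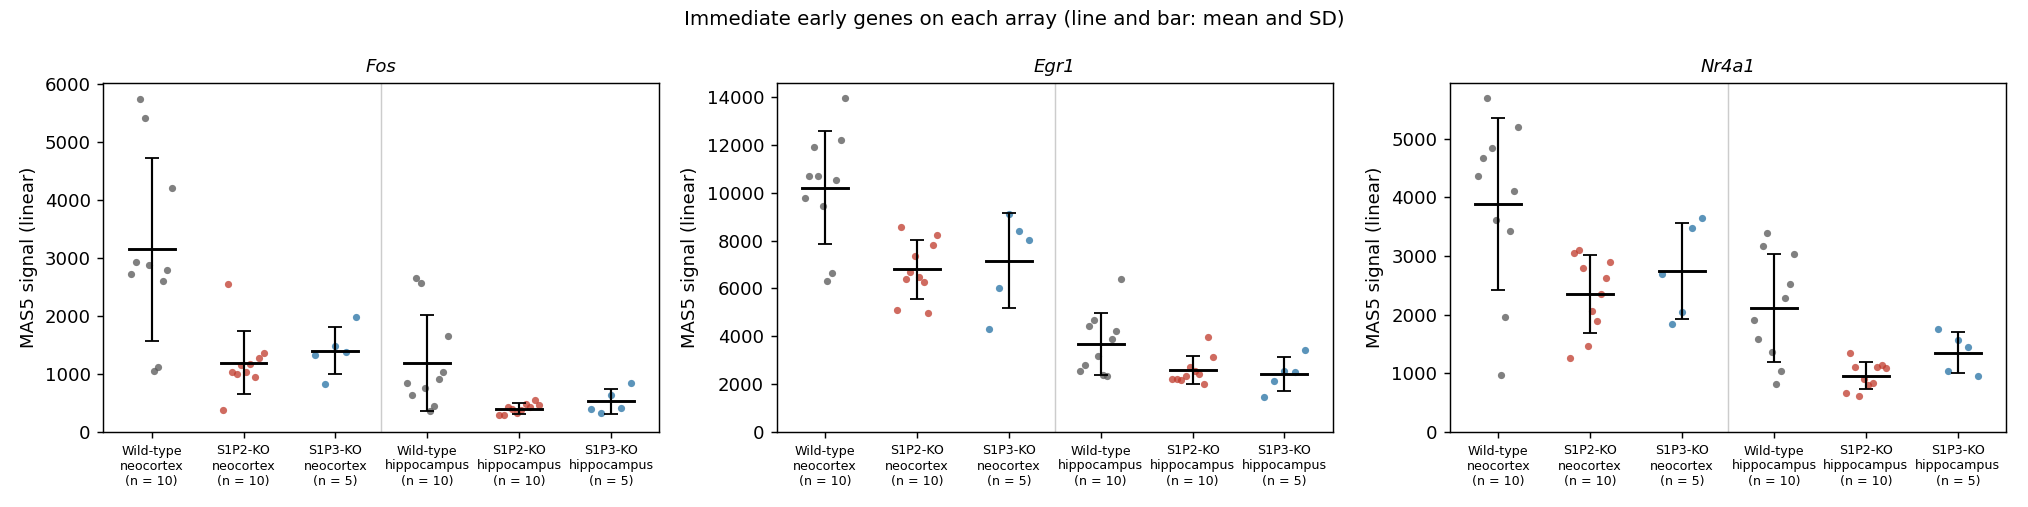
Signal of Fos, Egr1 and Nr4a1 on each array, with the linear MAS5 signal on the vertical axis and genotype and tissue on the horizontal axis; points are arrays, and black lines and bars are means and SD. Fos in neocortex averages 3142 in wild-type, 1187 in S1P2-KO and 1398 in S1P3-KO, and wild-type arrays spread from 1052 to 5739.

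Cholesterol synthesis genes fell in S1P2-KO hippocampus too, with 15 of 16 members lower (camera adjusted p = 0.0129, and adjusted p = 0.0532 with an estimated correlation). Their mean differed by -0.14 ± 0.04 (permutation p = 0.00167, adjusted 0.0242) and was below the wild-type median on 9 of 10 arrays. Ebp, a sterol isomerase, differed by -0.29 ± 0.12 (limma adjusted p = 0.809) and Cyp51 by -0.26 ± 0.11 (adjusted p = 0.838). Astrocyte markers rose, with 15 of 22 members higher (camera adjusted p = 0.0176, and adjusted p = 0.0964 with an estimated correlation), but their mean of 0.10 ± 0.06 was within the spread between arrays (permutation p = 0.109). Gfap differed by 0.33 ± 0.12 (limma adjusted p = 0.809). The call on astrocyte markers was lost without wild-type replicate 1 or S1P2-KO replicate 2, with an adjusted p of up to 0.074.

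Choroid plexus genes, which mark a tissue next to the hippocampus rather than the hippocampus itself, were higher for all 12 measured members (camera adjusted p = 0.0205, and adjusted p = 0.64 with an estimated correlation). Their list mean differed by 0.30 ± 0.36, well inside the spread between arrays (permutation p = 0.398), and 7 of 20 left-out animals ended the call (adjusted p of up to 0.119, mean from 0.20 to 0.43). Cab39l differed by 0.27 ± 0.15 (limma adjusted p = 0.905) and Igf2, a growth factor secreted by choroid plexus and meninges, by 0.31 ± 0.25 (adjusted p = 0.93). Ttr, the transthyretin that choroid plexus secretes, ran from 27.3 to 33071 among the wild-type hippocampus arrays alone. Microglia and macrophage genes did not pass camera (adjusted p = 0.0927), although their list mean was -0.11 ± 0.02 and lay below the wild-type median on 10 of 10 arrays (permutation p = 0.00035, adjusted 0.0101). Over single genes, 0 of 8534 probe sets were called by limma and 473 had an unadjusted p under 0.05. The count was 1 without wild-type replicate 6.

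In neocortex labelled S1P3-KO, cholesterol synthesis genes were lower than in wild-type, with 13 of 16 members lower (camera adjusted p = 3.15e-05, and adjusted p = 0.023 with an estimated correlation). The list mean differed by -0.25 ± 0.08 between 5 and 10 arrays and was below the wild-type median on all 5 (exact permutation p = 0.00167, adjusted 0.0483), and 5 members passed when adjusted over the list alone. Sqle, the squalene epoxidase, was 3394 ± 185 in wild-type and 2444 ± 655 in S1P3-KO, a difference of -0.54 ± 0.13 (limma adjusted p = 0.132). Idi1, an isomerase of isoprenoid units, differed by -0.58 ± 0.16 (adjusted p = 0.188).

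Immediate early genes fell in S1P3-KO neocortex with 21 of 29 members lower (camera adjusted p = 0.0118, and adjusted p = 0.589 with an estimated correlation). Their mean of -0.19 ± 0.13 was within the spread between arrays (exact permutation p = 0.266) and ran from -0.27 to -0.11 with 1 animal left out. Klf10, a growth-factor-induced transcription factor gene, differed by -0.66 ± 0.19 and Nr4a2, a nuclear receptor gene, by -0.59 ± 0.17 (limma adjusted p = 0.189 each). The call was lost without wild-type replicate 10, S1P3-KO replicate 1 or S1P3-KO replicate 2 (adjusted p of up to 0.258), and with the 3' to 5' ratio as a covariate (adjusted p = 0.123).

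Heat shock and endoplasmic reticulum stress genes rose with 21 of 25 members higher (camera adjusted p = 0.0118, and adjusted p = 0.437 with an estimated correlation), by a mean of 0.12 ± 0.08 (exact permutation p = 0.107), which ran from 0.06 to 0.19 with 1 animal left out. Manf, a secreted factor induced by unfolded protein, differed by 0.46 ± 0.13 (limma adjusted p = 0.189) and Pdia4, a disulfide isomerase, by 0.57 ± 0.20 (adjusted p = 0.315). Without S1P3-KO replicate 1 the adjusted p of this list was 0.305, and with the 3' to 5' ratio as a covariate it was 0.0603. Glucocorticoid response genes rose with 13 of 18 members higher (camera adjusted p = 0.0118, and adjusted p = 0.418 with an estimated correlation), by a mean of 0.13 ± 0.09 (exact permutation p = 0.179, from 0.09 to 0.18 with 1 animal left out), and 3 members passed adjusted over the list alone. Mt1, a metal-binding protein, was 15220 ± 1350 in wild-type and 19320 ± 1330 in S1P3-KO, a difference of 0.35 ± 0.10 (limma adjusted p = 0.202). Cdkn1a, a cell cycle inhibitor, differed by 0.49 ± 0.16 (adjusted p = 0.26). The glucocorticoid call was lost without wild-type replicate 6, S1P3-KO replicate 1 or S1P3-KO replicate 2 (adjusted p of up to 0.185).

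Over single genes limma called 0 of 8534 probe sets in S1P3-KO neocortex, with 895 at an unadjusted p under 0.05. The count was 10 without S1P3-KO replicate 3, 2 without wild-type replicate 10 and 1 without S1P3-KO replicate 4. With the 3' to 5' ratio as a covariate it was 23, among them Spock1, Sdc4 and Mt1, which were higher in S1P3-KO, and Mef2c, which was lower.

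In neocortex labelled S1P3-KO, Gfap was 1112 ± 242 in wild-type and 1616 ± 521 in S1P3-KO, a difference of 0.51 ± 0.16 (limma adjusted p = 0.233), with 4 of 5 arrays above every wild-type array. In hippocampus labelled S1P3-KO, Gfap rose. Its brighter probe set was 2558 ± 465 in wild-type (n = 10) and 4733 ± 1510 in S1P3-KO (n = 5), a difference of 0.84 ± 0.15 (limma adjusted p = 0.0273), and 4 of the 5 arrays lay above every wild-type array. Its dimmer probe set rose by 0.64 ± 0.12 (adjusted p = 0.0379). Kdelr1, a receptor that returns proteins to the endoplasmic reticulum, fell by 0.56 ± 0.10 from 4185 ± 360 to 2851 ± 384 (adjusted p = 0.0273). These 3 were the only calls among 8534 probe sets, with 814 at an unadjusted p under 0.05. S1P3-KO replicate 5, the array of high 3' to 5' ratio, carried the highest Gfap signal of all, 7108. Without it Gfap was higher by 0.69 on both probe sets, of which the dimmer passed (limma adjusted p = 0.0477) and the brighter did not (adjusted p = 0.0578). Kdelr1 was then at -0.53 ± 0.11 (adjusted p = 0.0578), and the only other call was Sdc4, a cell surface proteoglycan, at 0.85 (adjusted p = 0.00593). Fitting only the 2 genotypes gave 0 calls, as did leaving out wild-type replicate 1, 3 or 7 or S1P3-KO replicate 4. The count was 1 without wild-type replicate 5 or 10 or S1P3-KO replicate 1, 7 without S1P3-KO replicate 2 and 12 without S1P3-KO replicate 3. Without all 3 arrays of high 3' to 5' ratio it was 1, Sdc4.

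**Figure D4:**
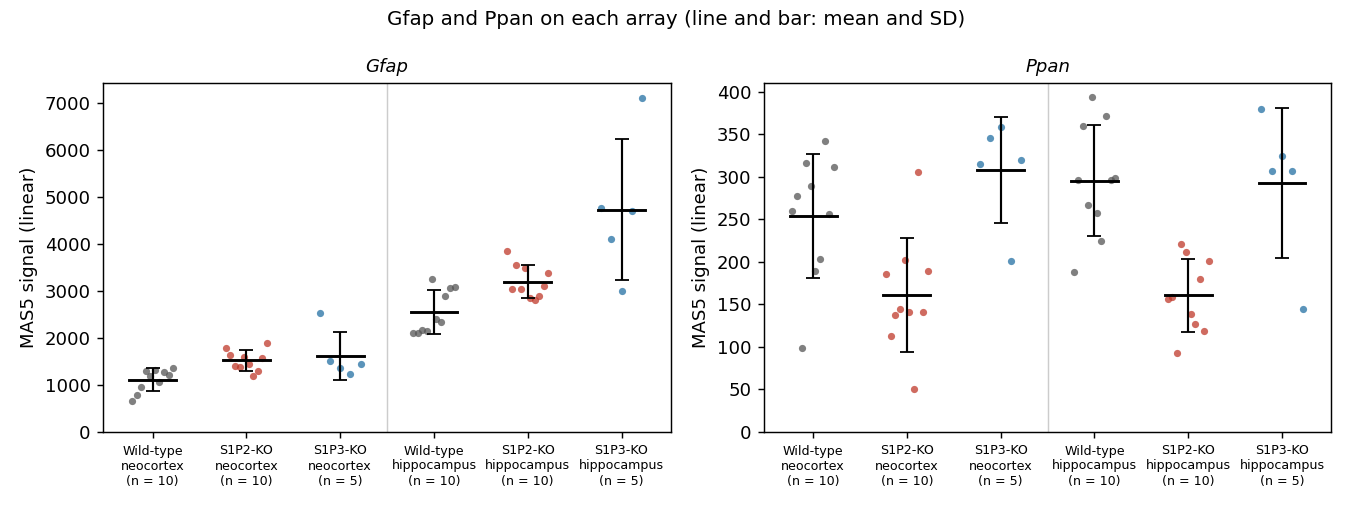
Signal of Gfap (left, brighter probe set) and Ppan (right) on each array, with the linear MAS5 signal on the vertical axis and genotype and tissue on the horizontal axis; points are arrays, and black lines and bars are means and SD. Gfap averages 2558 in wild-type and 4733 in S1P3-KO hippocampus, and Ppan averages 295 in wild-type and 160 in S1P2-KO hippocampus.

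Astrocyte markers as a list, Gfap included, did not pass in S1P3-KO hippocampus: 10 of 22 members were higher and the list mean differed by -0.01 ± 0.08 (camera adjusted p = 0.323). Without Gfap the median difference of the 21 others was -0.05. Without replicate 5 the list mean differed by 0.026 ± 0.085 (exact permutation p = 0.766, camera adjusted p = 0.458) and the median of the 21 others was -0.04. Cholesterol synthesis genes fell with 13 of 16 members lower (camera adjusted p = 0.00464, and adjusted p = 0.0263 with an estimated correlation). Their mean differed by -0.24 ± 0.05 and was below the wild-type median on all 5 arrays (exact permutation p = 0.000666, adjusted 0.0193). Fdft1, the squalene synthase, was 2934 ± 323 in wild-type and 2120 ± 345 in S1P3-KO, a difference of -0.48 ± 0.11 (limma adjusted p = 0.0967). Nsdhl, a sterol dehydrogenase, differed by -0.83 ± 0.24 (adjusted p = 0.237), and its lowest signal, 206, was again that of replicate 5. Without that array Nsdhl differed by -0.42 ± 0.13 (adjusted p = 0.39) and Fdft1 by -0.47 ± 0.11 (adjusted p = 0.2), and the mean of the cholesterol list differed by -0.21 ± 0.03 (exact permutation p = 0.002, camera adjusted p = 0.00254).

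Immediate early genes fell in S1P3-KO hippocampus with 23 of 29 members lower (camera adjusted p = 0.00128, and adjusted p = 0.298 with an estimated correlation). Their mean differed by -0.28 ± 0.10 and was below the wild-type median on all 5 arrays (exact permutation p = 0.0366, adjusted 0.133). Without replicate 5 it differed by -0.23 ± 0.08 (exact permutation p = 0.0999). Egr1 was 3690 ± 1300 in wild-type and 2412 ± 711 in S1P3-KO, a difference of -0.61 ± 0.20, and Jun, an AP-1 gene, differed by -0.34 ± 0.11 (limma adjusted p = 0.335 each). Heat shock and endoplasmic reticulum stress genes rose with 17 of 25 members higher (camera adjusted p = 0.0241, and adjusted p = 0.298 with an estimated correlation), by a mean of 0.07 ± 0.09 (exact permutation p = 0.306), or 0.15 ± 0.05 without replicate 5 and down to 0.04 without another animal. The endoplasmic reticulum chaperones Hsp90b1 and Hspa5 differed by 0.42 ± 0.11 (adjusted p = 0.187) and 0.46 ± 0.13 (adjusted p = 0.246). This call was lost without wild-type replicate 7, S1P3-KO replicate 2 or S1P3-KO replicate 3 (adjusted p of up to 0.138), with quantile normalization (adjusted p = 0.0646) and with the mean of all probe sets of a gene (adjusted p = 0.0607).

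**Figure D5:**
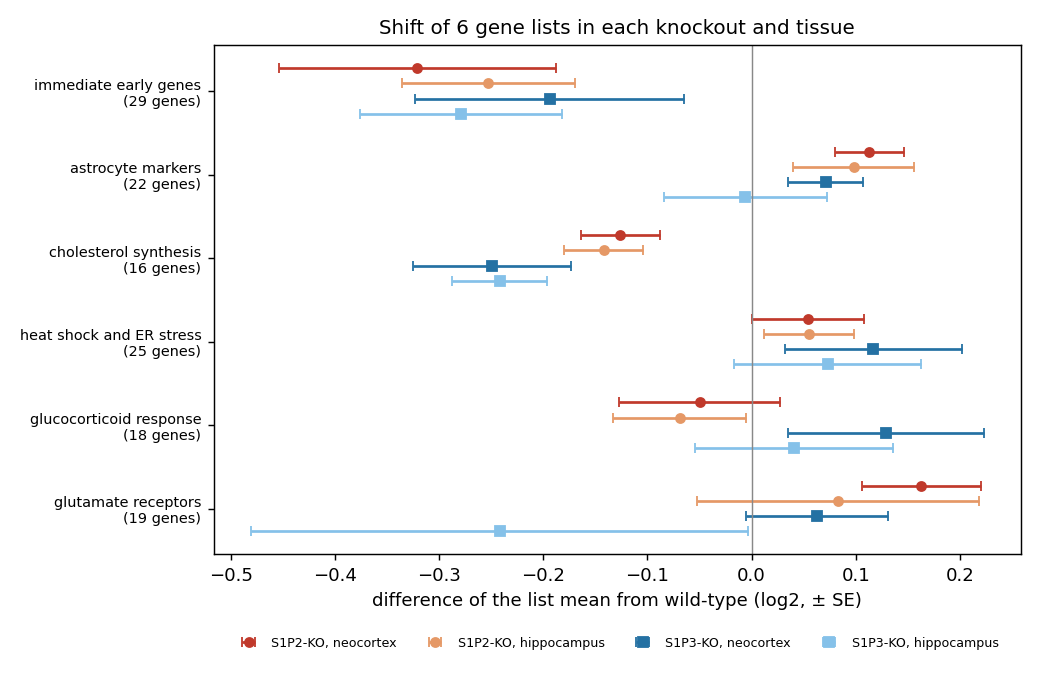
Difference of the mean log2 level of 6 gene lists between each knockout and wild-type, in log2 units on the horizontal axis, with the lists and their number of measured genes on the vertical axis; points are differences of group means and bars are SE, with circles for S1P2-KO and squares for S1P3-KO. Immediate early genes lie between -0.32 and -0.19, and cholesterol synthesis genes lie between -0.25 and -0.13.

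The knockouts were then set against each other. In neocortex S1P2-KO was below S1P3-KO in glucocorticoid response genes, with 15 of 18 members lower (camera adjusted p = 0.00123, and adjusted p = 0.313 with an estimated correlation). The list mean differed by -0.18 ± 0.10 (exact permutation p = 0.0866). Nfkbia, the inhibitor of NF-kB, was 1781 ± 372 in S1P2-KO and 2519 ± 386 in S1P3-KO, a difference of -0.50 ± 0.14 (limma adjusted p = 0.642), and Ddit4, a stress-induced inhibitor of mTORC1, differed by -0.54 ± 0.16 (adjusted p = 0.662). Without S1P3-KO replicate 1 the adjusted p of the list was 0.053. In hippocampus genes that mark thalamus were higher in S1P2-KO, with 10 of 11 members higher (camera adjusted p = 0.0153, and adjusted p = 0.265 with an estimated correlation). Their mean differed by 0.33 ± 0.08 (exact permutation p = 0.00167, adjusted 0.0483). Against wild-type hippocampus this list passed camera in neither knockout. Its mean lay above the wild-type median on 6 of 10 S1P2-KO arrays and below it on 4 of 5 S1P3-KO arrays. Whether thalamus was carried along in the dissection was not tested. Lef1, a transcription factor of Wnt signalling and a marker of thalamic neurons, was 1106 ± 244 in S1P2-KO and 526 ± 306 in S1P3-KO, a difference of 1.21 ± 0.23 (limma adjusted p = 0.0844). Prkcd, a protein kinase C isoform, differed by 0.45 ± 0.13 (adjusted p = 0.234). Without S1P3-KO replicate 5 the list mean differed by 0.31 ± 0.10 (exact permutation p = 0.005). S1pr3 differed by 0.82 ± 0.18 between S1P2-KO and S1P3-KO hippocampus (limma adjusted p = 0.152). Without that array S1pr3 differed by 0.78 ± 0.19 (adjusted p = 0.333), Lef1 by 1.28 ± 0.25 (adjusted p = 0.107) and Prkcd by 0.35 ± 0.13 (adjusted p = 0.607).

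Immediate early genes did not differ measurably between the knockouts: the list mean of S1P2-KO minus S1P3-KO was -0.13 ± 0.10 in neocortex (exact permutation p = 0.274) and 0.03 ± 0.07 in hippocampus (exact permutation p = 0.674). Cholesterol synthesis genes differed by 0.12 ± 0.08 in neocortex (exact permutation p = 0.0596) and 0.10 ± 0.05 in hippocampus (exact permutation p = 0.0536). Over single genes limma called 0 of 8534 probe sets in either tissue, with 506 in neocortex and 982 in hippocampus at an unadjusted p under 0.05. In hippocampus the count was 4 without S1P3-KO replicate 1, 1 without S1P2-KO replicate 1, 2 with array weights (Lef1 and Crb3) and 1 with the 3' to 5' ratio as a covariate (Crb3). In neocortex it was 1 with that covariate (Rps19) and 1 without S1P2-KO replicate 7 or S1P3-KO replicate 3.

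Across genes, which are not independent replicates, the log2 differences of both knockouts from wild-type correlated at 0.51 in neocortex and 0.25 in hippocampus. Both comparisons use the same wild-type arrays, and unchanged groups simulated against those arrays gave a median of 0.40 (95% range 0.20 to 0.58) in neocortex and 0.43 (0.08 to 0.67) in hippocampus, so both correlations lay inside the simulated range. The covariance in neocortex was 0.0217 against a simulated 0.0133 (0.0059 to 0.0239), a difference of 0.0084. In hippocampus it was 0.013 against 0.0175 (0.0033 to 0.0444), a difference of -0.0045, and both values were again inside the range. At an unadjusted p under 0.05, 153 probe sets were higher and 97 lower in both knockouts in neocortex, where simulation gave 27 (4 to 86) and 24 (2 to 86) and independent lists would give 20 and 19. In hippocampus 44 were higher and 43 lower in both, where simulation gave 26 (5 to 98) and 19 (3 to 95) and independent lists would give 9 and 13, so only the neocortex counts lay above the simulated range. When each knockout was set against a different part of the wild-type arrays, the correlation was 0.20 or 0.15 in neocortex and 0.01 or 0 in hippocampus, and the shared calls in neocortex were 70 or 58 higher and 29 or 23 lower.

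The difference of each knockout effect between the tissues was tested directly. For S1P2-KO limma called 0 of 8534 probe sets, with 222 at an unadjusted p under 0.05, and every list had an adjusted p of 0.904 or more. For S1P3-KO it called 0, with 438 at an unadjusted p under 0.05. Presynaptic proteins and glutamate receptors shifted further down in hippocampus than in neocortex for S1P3-KO (camera adjusted p = 0.0446 each, and adjusted p = 0.579 with an estimated correlation), with 16 of 24 and 15 of 19 members in that direction. Both calls rested on S1P3-KO hippocampus replicate 5, the array of high 3' to 5' ratio. Without it the mean difference was -0.04 instead of -0.32 for presynaptic proteins (camera adjusted p = 0.804) and -0.10 instead of -0.30 for glutamate receptors (camera adjusted p = 0.392). Among glutamate receptor genes, Homer1, a postsynaptic scaffold, differed by -1.09 ± 0.42 and Grin2a, an NMDA receptor subunit, by 1.04 ± 0.43. Among presynaptic genes, Syt5, a synaptotagmin, differed by -0.40 ± 0.15 and Nsf, an ATPase of vesicle fusion, by -0.44 ± 0.22 (limma adjusted p = 0.875 each). The same array held the lowest Nsf signal of its group, 4343, where the group averaged 12360 ± 4920, and without it Nsf differed by -0.11 ± 0.15, Syt5 by -0.239 ± 0.135, Homer1 by -0.78 ± 0.41 and Grin2a by 0.93 ± 0.45.

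Sex was compared within each tissue over the 3 genotypes, with 12 males and 13 females. In neocortex 5 of 8534 probe sets were called, 2 higher and 3 lower in females. Xist, the transcript that coats the inactive X chromosome, rose by 3.29 ± 0.29 (limma adjusted p = 1.2e-08), and Eif2s3x, the X-linked counterpart of Eif2s3y, rose by 0.59 ± 0.06 (adjusted p = 3.65e-07). Eif2s3y fell by 2.98 ± 0.24 (adjusted p = 1.88e-09), a probe set with no gene name here fell by 4.31 ± 0.18 (adjusted p = 1.31e-16), and Cplx2, a regulator of synaptic vesicle fusion, fell by 0.38 ± 0.07 (adjusted p = 0.0425). In hippocampus 5 were called, 3 higher and 2 lower. Xist rose by 2.53 ± 0.40, Eif2s3x by 0.66 ± 0.07 and Kdm6a, an X-linked histone demethylase that escapes inactivation, by 0.56 ± 0.09, while Eif2s3y fell by 3.11 ± 0.19 and the unnamed probe set was at -4.29 ± 0.14. Cplx2 differed by -0.43 ± 0.29 there (adjusted p = 0.952). Unadjusted p-values under 0.05 numbered 525 and 438.

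Among the lists, sex-linked genes as a set shifted up in females in both tissues (camera adjusted p = 3.23e-05 and 0.0125, and adjusted p = 0.00186 and 0.0782 with an estimated correlation). Of 5 measured members 4 were higher and 1, the Y-linked Eif2s3y, was lower. The direction of the list therefore follows from which members were measured. Heat shock and endoplasmic reticulum stress genes fell in female neocortex with 19 of 25 members lower (camera adjusted p = 0.00247, and adjusted p = 0.681 with an estimated correlation), among them Manf at -0.35 ± 0.09 (limma adjusted p = 0.407). In female hippocampus all 12 choroid plexus genes were lower (camera adjusted p = 3.4e-08, and adjusted p = 0.199 with an estimated correlation), among them Kl, a hormone co-receptor gene, at -0.99 ± 0.36 (limma adjusted p = 0.885). These genes mark a tissue next to the hippocampus and move together (estimated correlation 0.507), so the 12 are not independent. A difference in dissection was not tested, and list means were not compared between sexes. Markers of GABAergic neurons were higher in female hippocampus for 17 of 22 members (camera adjusted p = 0.0198, and adjusted p = 0.177 with an estimated correlation), among them Calb1, the calcium buffer calbindin, at 0.22 ± 0.07 (limma adjusted p = 0.823).

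The S1P2-KO effect was compared between females and males. Limma called 0 of 8534 probe sets in either tissue, with 658 in neocortex and 455 in hippocampus at an unadjusted p under 0.05. In hippocampus the effect on voltage-gated ion channels was lower in females, for 24 of 35 members (camera adjusted p = 0.0252), and that on glucocorticoid response genes was higher, for 14 of 18 (camera adjusted p = 0.0484). Neither held with an estimated correlation (adjusted p = 0.735 each). The potassium channel gene Kcnj11 differed by -1.83 ± 0.60 and the calcium channel gene Cacna1g by -0.77 ± 0.35. The kinase gene Sgk1 differed by 0.81 ± 0.38 and Errfi1, an inhibitor of EGF receptor signalling, by 0.48 ± 0.23 (limma adjusted p = 0.898 each). In neocortex 0 lists passed (smallest adjusted p = 0.0619). The count of probe sets was 1 in neocortex without wild-type replicate 1, 5, 6 or 7, and 1 in hippocampus without wild-type replicate 2.

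The tissues of wild-type mice differed in 889 of 8534 probe sets, 463 higher and 426 lower in hippocampus (1876 at an unadjusted p under 0.05). Hippocampus markers rose, with 7 of 13 members called higher and 1 lower (camera adjusted p = 2.6e-09, and adjusted p = 6.42e-07 with an estimated correlation). Dsp, a desmosome protein of granule cells, was 137 ± 105 in neocortex and 1209 ± 385 in hippocampus (n = 10 each), a rise of 2.74 ± 0.28 (limma adjusted p = 7.19e-11), and Lct, which encodes lactase, rose by 2.30 ± 0.18 (adjusted p = 2.69e-14). Npy2r, a neuropeptide Y receptor, rose by 2.79 ± 0.16 and Pkp2, a desmosome protein, by 2.60 ± 0.17. Neocortex markers fell, with 11 of 17 called lower and 1 higher (camera adjusted p = 1.41e-08, and adjusted p = 0.00111 with an estimated correlation). Mef2c, a transcription factor of cortical neurons, fell by 2.82 ± 0.51 from 7402 ± 857 to 1111 ± 822, and Igfbp6, a binding protein of insulin-like growth factors, fell by 2.06 ± 0.16 from 3978 ± 383 to 996 ± 207. Tnnc1, a troponin gene, fell by 2.22 ± 0.33.

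Genes of neuronal activity and signalling, and markers of striatum, were lower in wild-type hippocampus. Immediate early genes were called lower for 12 of 29 members and higher for 1 (camera adjusted p = 2.54e-07, and adjusted p = 0.113 with an estimated correlation), with Egr2 at -1.82 ± 0.33, Egr1 at -1.58 ± 0.19 and Fosb at -1.17 ± 0.18, while Jun rose by 1.08 ± 0.12. Neuropeptides and trophic factors that respond to seizures were called lower for 6 of 21 members and higher for Npy2r alone (camera adjusted p = 0.00775, and adjusted p = 0.0106 with an estimated correlation), with the neuropeptide genes Adcyap1 at -1.57 ± 0.20, Penk at -1.02 ± 0.18 and Npy at -0.94 ± 0.11. Striatum markers were called lower for 5 of 8 members (camera adjusted p = 1.64e-06, and adjusted p = 0.00363 with an estimated correlation), among them the phosphatase gene Ptpn5, which fell by 0.72 ± 0.09. Whether striatum was carried along in the dissection of neocortex was not tested. Voltage-gated ion channels were called lower for 7 of 35 members and higher for 2 (camera adjusted p = 0.00309, and adjusted p = 0.267 with an estimated correlation), and presynaptic proteins for 4 of 24 and 0 (camera adjusted p = 0.0125, and adjusted p = 0.267 with an estimated correlation). Cacna1g fell by 0.90 ± 0.18, and the vesicle fusion genes Stx1a and Snap25 were at -1.59 ± 0.35 and -0.40 ± 0.08.

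Glial and ventricular genes were higher in wild-type hippocampus. Astrocyte markers were called higher for 8 of 22 members and lower for 1 (camera adjusted p = 0.0116, and adjusted p = 0.0655 with an estimated correlation), with Gfap rising by 1.18 ± 0.15. Serpina3n, a protease inhibitor of reactive astrocytes, rose by 1.49 ± 0.12. Oligodendrocyte and myelin genes were called higher for 5 of 19 (camera adjusted p = 0.0239, and adjusted p = 0.152 with an estimated correlation), among them Cldn11, a tight junction protein of myelin, by 0.44 ± 0.13 and Car2, a carbonic anhydrase, by 0.35 ± 0.11. Choroid plexus genes were called higher for 4 of 12 (camera adjusted p = 0.00542, and adjusted p = 0.296 with an estimated correlation), among them Ttr by 4.28 ± 1.16 (limma adjusted p = 0.00893) and Kl by 3.42 ± 0.46 (adjusted p = 1.71e-07). Homer3, a scaffold of glutamate receptors, rose by 1.81 ± 0.16, and St3gal5, which makes the ganglioside GM3, fell by 0.70 ± 0.09.

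Genes near the targeted loci were compared with the rest of the genome, since alleles of the donor strain can stay linked to a targeted gene. Within 10 Mb of S1pr2, 10 of 43 probe sets (23.3%) had an unadjusted p under 0.05 in S1P2-KO neocortex against 8.7% elsewhere (two-sided Fisher's exact p = 0.00352), and 5 of 43 (11.6%) in hippocampus against 5.6% (Fisher's exact p = 0.0897). Ppan, a ribosome assembly factor gene inside that window, was 254 ± 72.8 in wild-type and 161 ± 66.6 in S1P2-KO neocortex, a difference of -0.60 ± 0.21 (limma adjusted p = 0.357). In hippocampus it was 295 ± 65.3 and 160 ± 42.5, a difference of -0.78 ± 0.17 (adjusted p = 0.282), and all 10 S1P2-KO arrays lay below its wild-type median. Within 10 Mb of S1pr3, 6 of 83 probe sets (7.2%) had an unadjusted p under 0.05 in S1P3-KO neocortex against 10.4% elsewhere (Fisher's exact p = 0.467), and 7 of 83 (8.4%) in hippocampus against 9.4% (Fisher's exact p = 1).

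A further 11 lists passed in 0 of the comparisons, with a camera adjusted p of at least 0.0568. They hold the receptors for sphingosine 1-phosphate and lysophosphatidic acid, sphingolipid metabolism, GABA receptors, interferon response, reactive astrocytes, microglia, oligodendrocyte precursors, endothelial cells, red blood cells and the fixed neighbours of S1pr2 and of S1pr3.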

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

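The tests of an effect in S1P2-KO alone, of left-out wild-type animals, of the array with a high 3' to 5' ratio and of position near the targeted gene were chosen after the result was seen, and the tests of RNA integrity, clock phase, astrocyte share and the other splits of the samples were written before.

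Camera called immediate early genes lower in S1P2-KO, the genotype with seizures, and also in S1P3-KO, with the same wild-type arrays on the other side, but with an estimated correlation none of these calls held (adjusted p = 0.268 and 0.0964 in S1P2-KO neocortex and hippocampus, 0.589 and 0.298 in S1P3-KO). Whether the effect lies in S1P2-KO alone stays open in both tissues. In hippocampus the list mean of S1P3-KO was -0.28 ± 0.10 from wild-type, and the direct difference of the knockouts was 0.03 ± 0.07. The exact permutation p of S1P3-KO was 0.0366 before adjustment over the lists and 0.0999 without replicate 5. High wild-type levels would lower both knockouts alike. In neocortex S1P3-KO differed by -0.19 ± 0.13 (exact permutation p = 0.266). How far the neocortex difference rests on 1 or 2 wild-type animals stays open. The permutation p of the S1P2-KO list mean rose to 0.103 without wild-type replicates 3 and 10. Of 45 left-out pairs 28 gave a p of 0.05 or more, and a smaller group alone raises p. The shift stayed negative, from -0.48 to -0.23, and the lowest p was 0.000366. The wild-type arrays set apart were low rather than high: replicates 6 and 7 lay at 9.704 and 9.822, the others from 10.384 to 10.8. RNA integrity stays open: the shift was -0.278 ± 0.136 with the 3' to 5' ratio as a covariate (linear model p = 0.0546). Without the covariate it was -0.321 ± 0.125 (linear model p = 0.0179), so most of its size was kept while its p passed 0.05. Clock phase stays open too. A clock score of 10 genes, from which Hlf fell out as too dim, differed by -0.092 ± 0.08 (95% interval -0.26 to 0.08).

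Gfap was higher in S1P3-KO hippocampus, where seizures are not reported. A higher share of astrocytes as the main cause is argued against over the other 21 astrocyte markers. Their median difference was -0.051 (95% bootstrap interval -0.11 to 0.07), below 0.42, the bound that a rule written beforehand drew from the change of Gfap. That interval resamples markers and holds no spread between animals. The list mean per array, Gfap included, ran from 11.652 to 12.033 in S1P3-KO and from 11.627 to 11.985 in wild-type. A smaller rise in the share of astrocytes stays open. The array with a 3' to 5' ratio of 4.46 stays open as part of the cause, because without it, with 4 arrays left in the group, the brighter Gfap probe set was at 0.685 ± 0.132 and missed the threshold (limma adjusted p = 0.0578), while the dimmer was at 0.69 ± 0.127 and passed (adjusted p = 0.0477). That array has no part in neocortex, where Gfap differed by 0.51 ± 0.16 in S1P3-KO without passing (limma adjusted p = 0.233). A change of astrocytes with genotype that touches Gfap more than other markers is a hypothesis that was not tested.

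Ppan was lower in S1P2-KO in both tissues. RNA integrity is argued against, since with the 3' to 5' ratio as a covariate Ppan stayed at -0.607 ± 0.233 in neocortex and -0.80 ± 0.16 in hippocampus. Its position near the targeted gene, where alleles of a donor strain or the targeted change itself could alter it or its probes, stays open: the share of neighbours with an unadjusted p under 0.05 was raised in neocortex (Fisher's exact p = 0.00352) but not past 0.05 in hippocampus (Fisher's exact p = 0.0897).

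Of 185 groups of arrays tested for a value far from the others, 13 (7%) held one, and chance gives about 1 in 20. The 3' to 5' log2 ratio was far above the rest of its hippocampus group in wild-type replicate 4 (1.2, others 0.26 to 0.75), S1P2-KO replicate 7 (1.37, others 0.02 to 0.52) and S1P3-KO replicate 5 (4.46, others 0.4 to 0.52). In neocortex, Fos was 378.2 in S1P2-KO replicate 1 (others 938.4 to 2539). Wild-type replicate 3 held Ppan at 98.6 (others 189.3 to 342.2) and Grin2a at 115 (others 235.2 to 471). Among the other wild-type neocortex arrays, Kl was 108.3 in replicate 7 (others 14.9 to 51.3), Pkp2 was 128.6 in replicate 10 (others 289.9 to 457.1) and Serpina3n was 725.9 in replicate 1 (others 977 to 1254). In hippocampus, Nsdhl was 206.2 in S1P3-KO replicate 5 (others 925.6 to 1130). Wild-type hippocampus replicate 3 held Homer1 at 65.4 (others 247 to 464) and Cacna1g at 131.6 (others 405.6 to 640.4), and Igfbp6 was 498.4 in wild-type replicate 1 (others 865.4 to 1238).

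The S1P3-KO effect differed between the tissues for glutamate receptors (camera adjusted p = 0.0446) and for presynaptic proteins (camera adjusted p = 0.0446), with adjusted p = 0.579 each with an estimated correlation. Without S1P3-KO hippocampus replicate 5, the array with a 3' to 5' ratio of 4.46, neither passed (camera adjusted p = 0.392 and 0.804), so these 2 calls are not put down to genotype. The S1P2-KO effect in hippocampus differed between the sexes for voltage-gated ion channels (camera adjusted p = 0.0252) and glucocorticoid response genes (camera adjusted p = 0.0484). With an estimated correlation the adjusted p of these 2 lists was 0.735 each.

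Each count was set against 100 splits of the same arrays into groups of the same sizes, the real split included. Few splits, by a cut-off set beforehand and without adjustment over the tests, reached the following counts. In S1P3-KO hippocampus 2 splits gave as many as the 3 probe sets called. For sex it was 2 splits in neocortex (5 probe sets, highest other 14) and 3 in hippocampus (5 probe sets, highest other 54). Between tissues it was 1 split (889 probe sets, highest other 510), and for the 4 lists of S1P3-KO neocortex 2 splits (highest other 4). That split test concerns the number of lists: with an estimated correlation only cholesterol synthesis held there (adjusted p = 0.023), and immediate early, heat shock and glucocorticoid genes did not (adjusted p = 0.589, 0.437 and 0.418). For S1P3-KO hippocampus the highest other split called 529 probe sets, which points to a structure of the samples. That split set wild-type replicates 1, 3 and 4 and S1P3-KO replicates 3 and 5 against the rest, and these hold the 3 highest 3' to 5' ratios of the 15 arrays. The test therefore cannot tell whether the 3 calls come from genotype or from such a structure. A count of 0 from limma is matched by all 100 splits, and the highest other count was 17 for S1P2-KO neocortex and 2 for S1P2-KO hippocampus. It was 2 for S1P3-KO neocortex, 8 and 5 between the knockouts in neocortex and hippocampus, 0 and 3 for the tissue difference of S1P2-KO and S1P3-KO, and 2 for the sex difference of S1P2-KO in each tissue. Unadjusted p-values under 0.05 numbered 222 to 982 in these comparisons. Chance was not excluded for the number of lists in S1P2-KO neocortex (4 lists, 10 splits, highest other 7), S1P2-KO hippocampus (4 lists, 12 splits, highest other 6) or S1P3-KO hippocampus (3 lists, 19 splits, highest other 8). The same holds between the knockouts in neocortex (1 list, 60 splits, highest other 4) and hippocampus (1 list, 73 splits, highest other 6).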

How the results depend on the processing

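The fits without the 3 hippocampus arrays of high 3' to 5' ratio, and the tissue differences of lists without S1P3-KO replicate 5, were chosen after the data were seen, as were the list means and, for the gene lists, the 3' to 5' ratio as a covariate and each left-out array. Of the alternative values, 358 counts stayed within 1.5 times the reported one and 52 did not. All 120 values of the targeted genes kept their direction and their side of the threshold, 356 list results did so, 42 lost the threshold, and none turned direction. With quantile and loess normalization the median log2 difference of all probe sets lay between -0.021 and 0.015 in every comparison, against -0.017 to 0.007 without, and they gave 945 and 909 calls between the tissues against 889. Arrays carry no depth, and MAS5 signals near background limit what dim genes can show. For the changes below the cause was not tested, except where fewer arrays or fewer probe sets entered.

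Counts of probe sets moved as follows. Without an offset, sex gave 2 in neocortex and 3 in hippocampus, and with the filter at the 50th percentile 1 and 2. Array weights gave 8 for S1P2-KO neocortex and 2 between the knockouts in hippocampus. The 3' to 5' ratio as a covariate gave 1 for S1P2-KO neocortex, 23 for S1P3-KO neocortex, and 1 between the knockouts in each tissue. Only the 2 genotypes compared gave 0 for S1P3-KO hippocampus, where 814 had an unadjusted p under 0.05 in limma over 3 genotypes, and without the 3 arrays of high ratio it was 1.

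With 1 animal left out, counts ran from 0 to 8 in S1P2-KO neocortex, 0 to 1 in S1P2-KO hippocampus, 0 to 10 in S1P3-KO neocortex and 0 to 12 in S1P3-KO hippocampus. Between the knockouts they ran from 0 to 1 in neocortex and 0 to 4 in hippocampus, for the sex difference of S1P2-KO from 0 to 1 in either tissue, for sex from 4 to 6 and 5 to 6, and between tissues from 699 to 874. The counts with the full set of arrays, by limma, were 0 except for S1P3-KO hippocampus, sex and tissue. S1pr2 in S1P2-KO ran from -0.16 to -0.03 in neocortex and -0.33 to -0.17 in hippocampus, and S1pr3 in S1P3-KO from -0.45 to -0.14 and -0.76 to -0.64.

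Numbers of gene lists past the threshold moved as follows. An estimated correlation gave 1 and 0 for S1P2-KO in neocortex and hippocampus, 1 and 1 for S1P3-KO, and 0 and 0 between the knockouts. The 3' to 5' ratio as a covariate gave 2 for S1P3-KO neocortex, and without the 3 arrays of high ratio S1P3-KO hippocampus had 5. Between the knockouts in neocortex, quantile and loess normalization gave 2 each. In hippocampus they gave 5 and 2, the mean of all probe sets of a gene gave 4, and leaving out S1P3-KO replicate 5 or the 3 arrays of high ratio gave 2 each.

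The labels number the replicates alike in all groups, and do not state that a number names 1 animal in both tissues. With the replicate number as a replicate block, S1pr3 in S1P3-KO hippocampus was at -0.69 ± 0.18 (limma adjusted p = 0.176), S1P3-KO hippocampus had 3 calls, and the wild-type tissues had 1073. After removal of the means of genotype, tissue and sex, arrays of the same number in both tissues had correlations from -0.27 to 0.22 with a median of 0.09, and 4 of 25 neocortex arrays correlated best with their own number.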

Other observations

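The 2 fits over both tissues, the values of Xist and the relation of immediate early genes between tissues were chosen after the data were seen.

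When the 2 tissues of each replicate number were averaged before the fit, 0 of 8534 probe sets were called in S1P2-KO against wild-type (limma, 10 and 10 averages, 766 at an unadjusted p under 0.05). Fos differed by -1.28 ± 0.26 and Gadd45b, a stress- and activity-induced gene, by -0.75 ± 0.16 (adjusted p = 0.112 each), and Sdc4 by 0.47 ± 0.09 (adjusted p = 0.0971). In S1P3-KO 11 were called, 9 higher and 2 lower. Ramp2, a subunit of the adrenomedullin receptor, rose by 0.49 ± 0.08 and Sdc4 by 0.60 ± 0.11 (limma adjusted p = 0.0195 each), Gfap rose by 0.68 ± 0.13 (adjusted p = 0.0206) and Gjb6 by 0.37 ± 0.07 (adjusted p = 0.0228), while Mvd fell by 0.67 ± 0.12 (adjusted p = 0.0195). Without replicate 5 of S1P3-KO in either tissue only Sdc4 was called there, at 0.70 ± 0.10 (adjusted p = 0.00341), Gfap was at 0.61 ± 0.13 (adjusted p = 0.105), and in S1P2-KO 2 were called, Sdc4 among them (adjusted p = 0.0236). Spock1, an extracellular proteoglycan gene within the window around S1pr3, differed by 0.78 ± 0.18 with all arrays (adjusted p = 0.0762).

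Between the knockouts the averages gave 0 calls (limma, 1039 at an unadjusted p under 0.05). S1pr3 differed by 0.65 ± 0.12, Lef1 by 0.79 ± 0.15 and Ppan by -0.81 ± 0.18 (adjusted p = 0.104 each). A fit of all 50 arrays with the replicate number as a random block called more, 10 probe sets for S1P2-KO, 51 for S1P3-KO and 18 between the knockouts, and 35, 77 and 6 without the 3 arrays of high 3' to 5' ratio. It sets 1 correlation of 0.131 between the tissues for all genes. The list mean of immediate early genes on the wild-type arrays went together far more closely, as given below, so the errors of that fit may be too small for these genes. The correlation of single genes such as Fos between tissues was not computed. Fos, with an adjusted p of 0.00195 in that fit, had 0.0764 and 0.404 in the single tissues, and its call is not relied on.

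Genes of oligodendrocyte precursors and neurogenesis did not pass camera in S1P2-KO neocortex (adjusted p = 0.294), but their list mean differed by -0.11 ± 0.02 (permutation p = 0.0008, adjusted 0.0232), with 14 of 17 members lower.

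Xist, which was compared among females only, was 1118 ± 632 in wild-type neocortex (n = 5), 540 ± 189 in S1P2-KO (n = 5) and 228 ± 104 in S1P3-KO (n = 3). In hippocampus it was 1101 ± 880, 365 ± 272 and 84.0 ± 38.9. Against wild-type the exact permutation p was 0.127 and 0.0357 in neocortex and 0.254 and 0.0536 in hippocampus for S1P2-KO and S1P3-KO, and the smallest value after adjustment over the 4 tests was 0.107.

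The mean level of immediate early genes in the wild-type neocortex arrays went with that of the hippocampus array of the same replicate number (n = 10). Pearson's r was 0.93 (permutation p = 2e-04) and Spearman's rho was 0.92 (permutation p = 0.00058), and r was 0.81 without the 2 arrays farthest from the median in neocortex. This was the only such relation computed.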
